A study of Mus musculus with 5 samples.

How the data were processed

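4C-seq with DpnII as first and Csp6I as second restriction enzyme was run on 5 mouse libraries with a bait at the Pik3r1 promoter region, per the labels' protocols. Reads began at 50 nt and were 29 nt long after removal of the bait sequence in DP thymocytes, WT muscle replicate 1 and GRko muscle replicate 1, and 23 nt in WT muscle replicate 2 and GRko muscle replicate 2, per the labels. The authors deposited raw read counts per restriction fragment of chromosome 13, not normalized, with the bait's position in the first line, per the file headers. Demultiplexing with bcl2fastq, alignment with Bowtie 1.0.0 and the mm10 build are named in the submitters' processing notes; how reads were assigned to fragments, and whether fragments were filtered, is not given in the sources used here. Up to 3 fragments nearest the bait were missing from some files, all within 1247 bp of it. Without molecular identifiers PCR copies of a ligation product cannot be told from separate products, and short reads align to unique positions less often in repeated gene families such as the histone genes. The count tables hold no other chromosome, so contacts with other chromosomes were not analysed here.

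The tested region spanned 1.5 Mb on either side of the bait without the nearest 10 kb, which holds undigested and self-ligated products. It had 7284 fragments in 300 bins of 10 kb. Library sizes were the reads in these bins, from 634064 in GRko replicate 2 to 4902222 in thymocytes. Bins with at least 10 reads in at least 2 libraries were tested with edgeR 4.0.16 (quasi-likelihood, R 4.3.3) and Benjamini-Hochberg adjustment at 0.05. GRko was compared with WT muscle in the 4 muscle libraries. Thymocytes were compared with WT muscle in a fit of all 5 libraries, so the single thymocyte library is assumed to vary like the muscle libraries. Beyond 1.5 Mb, fragments with at least 1 read were counted per 500 kb window and tested the same way, with covered far fragments as library size. Shares by distance and side were compared by exact two-sided permutation tests. Expected reads for contact peaks came from a non-increasing isotonic fit (scikit-learn 1.9.0) of log2 mean reads per fragment over distance, in classes of 10 kb up to 100 kb and 50 kb beyond, chosen after fits on single bins gave extreme ratios far from the bait.

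Genes and coordinates came from an annotation of GRCm38.p6, which has the coordinates of mm10, and all 16 neighbouring and 17 listed far genes were matched. It carries no strand, so start sites were unknown. The design fixed before the data were examined had asked for start-site bins. Gene spans, as far as they lay in the tested region, were used instead near the bait. Gene midpoints placed the far lists. Named bins and windows followed a rule fixed at the same time: up to 10 bins or 5 windows per direction with the largest ratios among those past the threshold and on the same side in every pair of libraries, or, where none passed, the 3 with the smallest p in each direction, the fixed genes, and the 5 highest contact peaks per group. A far window that this rule names is not reported here.

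Alternatives were TMM normalization, all chromosome 13 reads as library size, DESeq2 1.42.0, no filter on low counts, other bin and window sizes, 25 kb left out around the bait, capped or covered fragments, each replicate left out, the replicate number as a block, and other sets of libraries. Bins of 100 kb, the same number of fragments from every library, a minimum of 10 reads per fragment, and the overlap of contact peaks with the expected value fitted on each side were added after seeing the data. Intervals for the thymocyte library are 95% Wilson intervals, and a count of 0 was set against a floor of 3 counts.

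The tests were tested on simulated negative binomial counts, 20 data sets each, drawn from the real means, library sizes and the common spread of each comparison. The thymocyte library was drawn with that same spread. The simulations therefore cannot check the assumption that it varies like the muscle libraries. For near-cis bins 0% of changes of 2-, 4- or 16-fold between the genotypes were recovered with 60 of 270 bins changed; between thymocytes and WT muscle (60 of 284 bins) recovery was 0%, 0.25% and 0%. For far windows between thymocytes and WT muscle with 20 of 185 changed, 11.5% of 2-fold and 66.5% of 4-fold changes were recovered and 0.455% of unchanged windows were called. A harsher simulation, run first, with 60 of 185 windows changed up to 16-fold, called 37.6% of unchanged windows, because strong changes in many windows alter the library total. With the totals before the change that share was 1.08%, and with TMM 1.04%. Between the genotypes it was 45.9%, with 60 of 165 windows changed. The smaller set of 20 changed windows was added after that result. In the real far windows TMM moved the log2 ratios of thymocytes over WT muscle by a median of 0.11, and 18 of the 20 windows called were called with it too, among 24 in all.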

Results

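Contacts of the Pik3r1 promoter region were measured by 4C-seq, which sequences the DNA fragments ligated to a chosen bait fragment after crosslinking, in mouse skeletal muscle and thymus. Pik3r1 encodes the p85α regulatory subunit of phosphoinositide 3-kinase. In mm10 coordinates the bait lay on chromosome 13 at position 101766365, inside the Pik3r1 gene (101680761 to 101768217) and 1852 bp from its higher-coordinate end. The 5 libraries comprised 1 of CD4+/CD8+ double-positive (DP) thymocytes from wild-type mice aged 4 weeks, 2 of wild-type (WT) muscle and 2 of GRko muscle from mice aged 10 to 12 weeks. GRko is read here as a knockout of the glucocorticoid receptor, from what is known of the study. The receptor gene lies on another chromosome, so the counts did not check the genotype. Reads on chromosome 13 numbered 8993436 in DP thymocytes, 5750330 and 2582156 in WT muscle replicates 1 and 2, and 3106596 and 1317351 in GRko muscle replicates 1 and 2. They covered 13581, 9389, 4691, 5041 and 3536 of about 292200 restriction fragments, in the same order of libraries. Because each covered fragment carried many PCR copies, the number of covered fragments is a closer guide to the number of ligation events than the read total. The labels do not say whether replicates came from separate animals, so p-values measure the spread between libraries. Intervals given for the single thymocyte library cover counting error only. Those on reads count PCR copies as separate and are too narrow.

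The comparison of GRko with WT muscle asks whether loss of the receptor changes where the Pik3r1 promoter region makes contact. In both genotypes most contacts within 1.5 Mb of the bait lay on the higher-coordinate side, toward Cd180 and Mast4. That side held 71.0% ± 0.518 of the reads in WT muscle and 66.4% ± 0.432 in GRko muscle (SD, n = 2 each), leaving out 10 kb on either side of the bait. The gene body of Pik3r1 itself took 11.0% ± 0.0696 of the reads in WT and 16.9% ± 2.84 in GRko muscle (SD, n = 2 each). The difference in the side of contact was -4.59 percentage points. It was -4.65 between the libraries read at 29 nt and -4.53 between those read at 23 nt. An exact two-sided permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow, and 0.81 after adjustment over 17 zones and sides. With covered fragments in place of reads the genotypes differed by -0.028 points, less than the spread between replicates. The match between the pairs of equal read length was lost in other settings. With 25 kb left out, WT replicates 1 and 2 held 73.2% and 72.7%, and GRko replicates 68.4% and 72.0%. Counting fragments with at least 10 reads, they held 64.6% and 72.2%, and 66.7% and 67.5%.

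Among distance zones, the lower side between 10 and 50 kb from the bait, inside the Pik3r1 gene body, held 8.08% ± 0.701 of the reads in WT muscle and 13.6% ± 2.37 in GRko muscle. The higher side between 500 and 1000 kb held 24.5% ± 2.83 in WT and 20.9% ± 0.832 in GRko muscle. Both zones had p = 0.333 in the exact permutation test. With covered fragments in place of reads, the libraries of the genotypes overlapped in both zones. The higher zone then held 23.3% and 26.1% in WT and 24.2% and 24.0% in GRko muscle. The lower zone held 2.61% and 4.49% in WT and 3.49% and 6.21% in GRko muscle. In the lower zone this share rose as the covered fragments of a muscle library fell, from 3100 in WT replicate 1 to 1062 in GRko replicate 2. The overlap there therefore cannot tell whether the genotypes differ. Reads within 1.5 Mb made up 63.7% ± 2.33 of all chromosome 13 reads in WT and 63.5% ± 6.13 in GRko muscle.

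No 10 kb bin passed the test between the genotypes. With edgeR's quasi-likelihood test, 0 of 270 bins had an adjusted p under 0.05, 4 had an unadjusted p under 0.05, and DESeq2 called 4 bins, 3 higher and 1 lower in GRko muscle. The bin at 102640001 to 102650000, which overlaps no annotated gene and lies 879 kb from the bait on the side of Cd180, held 26036 and 12287 reads in the WT libraries and 26050 and 19254 in the GRko libraries (log2 ratio 1.33 ± 0.757, SE). The bin at 101300001 to 101310000, over the predicted gene Gm36427, held 3552 and 11 reads in WT and 6454 and 5849 in GRko muscle. The bin at 100560001 to 100570000, over Gm8847, held 10 and 0 reads in WT and 10100 and 35 in GRko muscle. On the other side of the ranking, the bin at 101620001 to 101630000 held 7689 and 23174 reads in WT and 1655 and 230 in GRko muscle. Bins at 100970001 and 101570001 had log2 ratios of -4.63 ± 2.03 and -3.05 ± 1.36. Replicates of a genotype differed so much within a bin that, in data simulated at this spread, 0% of bins changed 16-fold were recovered. The simulation gave every bin the same spread, although the SE of the bins named here ran from 0.757 to 3.90. At the simulated spread the count of 0 sets no useful limit on differences between single bins. Bins with less spread were not simulated.

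Of the 16 neighbouring genes fixed before the data were examined, 15 lay at least partly in the tested region; Smn1 lay outside. None passed the test in edgeR, either over all bins or adjusted over the list alone, 1 had an unadjusted p under 0.05, and DESeq2 called 0. Pik3r1 was the gene with that unadjusted p, with a log2 ratio of GRko over WT of 0.62 ± 0.25 (SE), an adjusted p of 0.98 and 0.231 adjusted over the list alone. Without GRko replicate 1 its adjusted p was 0.026 and it alone was called. Ratios were above 0 for 8 genes and below 0 for 7. Slc30a5, a zinc transporter, held 0.762% ± 0.356 of the reads in WT and 0.286% ± 0.323 in GRko muscle. Mast4, which encodes a microtubule-associated kinase and spans 102732486 to 103335099, held 6.19% ± 1.19 and 4.81% ± 1.65. Cd180, which encodes a Toll-like receptor homologue of B cells, held 0.0732% ± 0.0541 and 0.0941% ± 0.0998.

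DP thymocytes distributed their contacts differently from WT muscle. Only 46.6% of their reads within 1.5 Mb lay on the higher-coordinate side (95% Wilson interval 46.6 to 46.6), against 71.3% and 70.6% in the WT muscle libraries. That interval counts every PCR copy as a separate read and is too narrow. The difference from the WT mean was -24.4 percentage points, with all 4 muscle libraries between 66.1% and 71.3%. The lower-coordinate side, which holds Slc30a5, Ccnb1, Cdk7 and Ocln, held 53.4% of thymocyte reads. Shares on either side are parts of the same total, so a gain on the lower side cannot be told from a loss on the higher side. Tissue and age differed together, and a single thymocyte library has no replicate check.

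**Figure D1:**
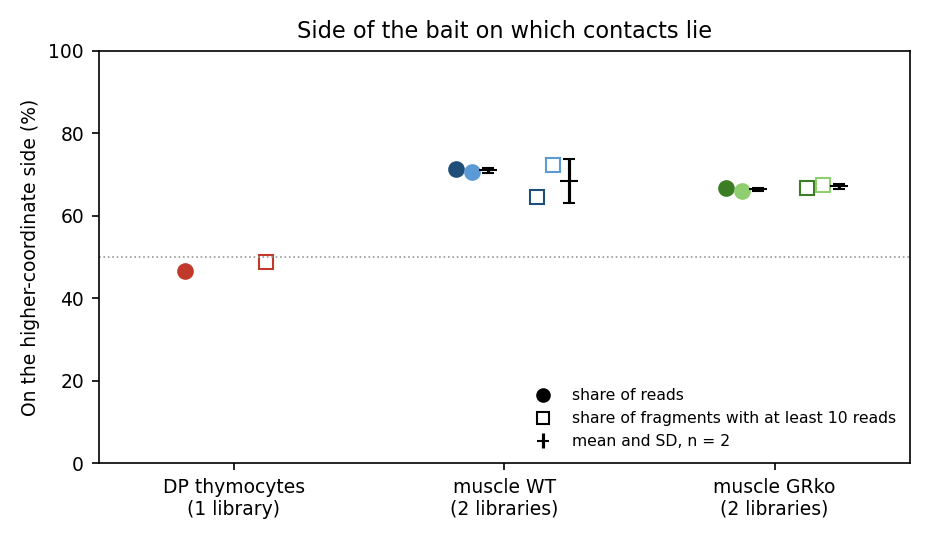
Share of contacts on the higher-coordinate side of the bait (%), within 1.5 Mb and without 10 kb on either side, for each library. Filled circles are shares of reads and open squares shares of fragments with at least 10 reads; bars give mean and SD of 2 libraries. DP thymocytes lie at 46.6% of reads, below the 66.1% to 71.3% of the muscle libraries.

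The largest zone difference was between 500 and 1000 kb. On the higher side this zone held 11.8% of reads in thymocytes (95% Wilson interval 11.7 to 11.8) and 24.5% ± 2.83 in WT muscle. On the lower side it held 14.1% (14.1 to 14.2) and 6.95% ± 0.568. With covered fragments in place of reads, the higher side held 49.0% in thymocytes (95% Wilson interval 47.5 to 50.5) and 63.1% and 70.7% in WT muscle. The share within 10 kb of the bait was 15.9% in thymocytes and 12.7% ± 1.26 in WT muscle.

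**Figure D2:**
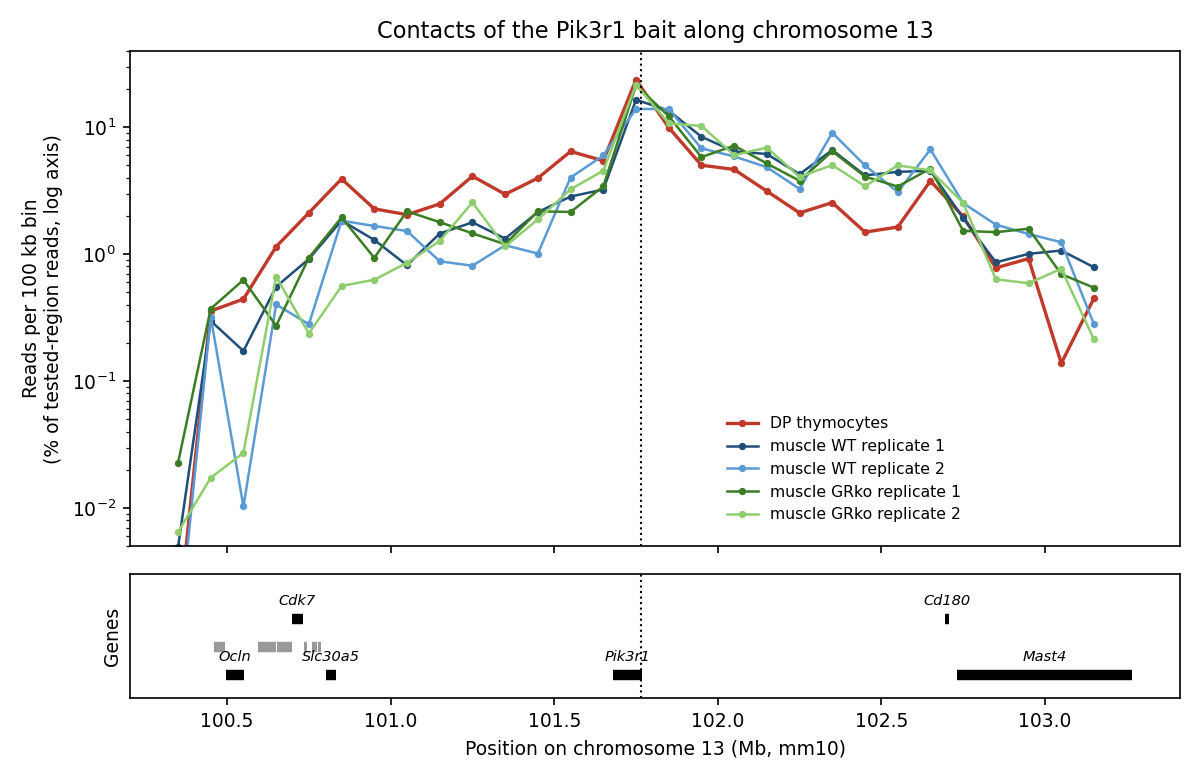
Reads per 100 kb bin, as percent of the tested-region reads on a log axis, against position on chromosome 13, for each library, with the fixed neighbouring genes drawn below to scale and the bait as a dotted line. Bins with values below the axis are not drawn. Thymocytes hold 2.55% of reads in the bin at 102300001, below the 5.03% to 9.04% of the muscle libraries.

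In 10 kb bins the spread between libraries was again wide. With edgeR, 0 of 284 bins passed, 4 had an unadjusted p under 0.05, and DESeq2 called 6, with 3 in each direction. In bins of 100 kb, a size chosen after the data were seen, edgeR called 3 of 31 and DESeq2 6, these 3 among them. The bin holding the bait, 101700001 to 101800000, was higher in thymocytes with a log2 ratio of 0.64 ± 0.194 (SE, adjusted p = 0.024). It held 23.7% of thymocyte reads, 16.5% and 13.9% of WT muscle reads, and 21.4% and 21.6% of GRko muscle reads. In covered fragments its ratio had the opposite sign (-0.72 ± 0.282, adjusted p = 0.061), but with 91.9% of its 186 fragments covered in thymocytes that ratio is held down. With the 1062 fragments of most reads from every library its log2 ratio was 0.11, and 0.18 and 0.050 against WT replicates 1 and 2. These ratios were small, so the direction of this bin stays unsettled. The adjoining bins at 102300001 and 102400001 were lower, with log2 ratios of -1.62 ± 0.406 and -1.62 ± 0.537 and adjusted p of 0.0056 and 0.038. All 3 had an adjusted p over 0.1 when either GRko library was left out, although the ratios stayed the same, since those libraries contribute only to the estimate of spread. Without WT replicate 2 the bins at 102300001 and 102400001 had adjusted p of 0.068 and 0.197, and without WT replicate 1 the second of them had 0.137. Counting covered fragments per 100 kb, all 13 bins on the lower side had ratios above 0, with a median log2 ratio of 0.81, and 12 of 15 on the higher side had ratios below 0, with a median of -0.46. Thymocytes covered up to 93.4% of the fragments of a bin there, a limit that by itself lowers their ratio. With the 1062 fragments of most reads from every library, a set chosen after the data were seen, they covered at most 39.5% in those bins. All 15 ratios on the higher side were then below 0 (median -0.70) and all 13 on the lower side above 0 (median 1.05). With a fixed number of fragments per library, fewer on the higher side means more elsewhere. In the test on all covered fragments, with the bin holding the bait, 29 bins were tested; none passed in edgeR, and 16 had an unadjusted p under 0.05. Without WT replicate 1, 18 of 28 passed, and without WT replicate 2, 2 of 29. Without either GRko library 0 passed, with 4 and 5 under an unadjusted p of 0.05. Against the mean of all 4 muscle libraries 17 of 29 passed, 9 higher and 8 lower.

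At 10 kb, the bin at 101440001 to 101450000 held 50077 reads in thymocytes and 3900 and 1 in WT muscle. Other reads given here are raw, out of 4902222 in the tested region in thymocytes and 2890841 and 1337018 in the WT libraries. The GRko libraries had 1699603 and 634064. The bin at 101590001, over Gm36553, held 39788 reads in thymocytes and 5194 and 19 in WT muscle, and that at 100560001, over Gm8847, 5904 against 10 and 0. Within Mast4, the bin at 103010001 held 287 reads in thymocytes and 1905 and 14639 in WT muscle, and the bin at 103020001 held 0 against 10422 and 220. The bin at 100420001, over Naip1, held 0 reads in thymocytes, 0 and 4182 in WT muscle, and 2 and 50 in GRko muscle.

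Among the fixed neighbouring genes, 14 of 15 had a ratio of thymocytes over WT muscle above 0, and Mast4 was the exception. With edgeR none was called over all bins or adjusted over the list alone, and 1 had an unadjusted p under 0.05; DESeq2 called 0. Pik3r1 held 17.7% of thymocyte reads (95% Wilson interval 17.6 to 17.7) and 11.0% ± 0.0696 of WT muscle reads (log2 ratio 0.69 ± 0.306, adjusted p = 0.99, and 0.374 adjusted over the list alone). Without GRko replicate 1 or replicate 2 Pik3r1 was called, although its log2 ratio stayed at 0.69. The spread within groups then came from the 2 WT libraries alone, which lay close together. GRko muscle held 14.9% and 18.9%, on either side of the thymocyte share, so this call does not set thymocytes apart from all muscle. Slc30a5 held 1.19% and 0.762% ± 0.356, and Mast4 3.57% and 6.19% ± 1.19 (log2 ratio -0.80 ± 0.547). Mrps36 held 16525 thymocyte reads and 551 and 7 WT muscle reads (log2 ratio 5.10 ± 3.84). These genes were tested over their whole spans, and most lie next to each other on the lower side, so their ratios are not independent.

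Bins whose reads per fragment were at least 2 times the value expected at their distance, in every library of a group, numbered 17 in WT muscle, 11 in GRko muscle and 36 in DP thymocytes, where a single library had to pass. The expected value came from both sides of the bait together, so the side on which these bins lie repeats the side share above. With the expected value fitted on each side they numbered 12, 12 and 33, of which 5, 5 and 18 lay on the higher side. Single muscle libraries had 44 to 50 such bins. With the expected value fitted on each side, single libraries had 33 to 61 such bins. The WT replicates then shared 12 where 7.28 would be shared by independent lists (Fisher's exact test, p = 0.0472, adjusted over 10 pairs 0.0787), and the GRko replicates 12 against 10.2 (adjusted p = 0.582). Across genotypes, WT replicate 1 shared 12 with GRko replicate 1 (6.50 expected, adjusted p = 0.048) and 6 with GRko replicate 2 (7.93, 0.582), and WT replicate 2 shared 17 (9.33, 0.0155) and 13 (11.4, 0.582). Thymocytes shared 13 and 11 with the WT replicates (4.29 and 6.16 expected, adjusted p = 0.000194 and 0.0631) and 15 and 9 with the GRko replicates (5.50 and 6.71, 0.000194 and 0.511). With a single expected value for both sides the WT replicates shared 17 against 7.33 (Fisher's exact test, p = 0.000111), the most of any pair, an overlap that includes the lean of both to the higher side. Neighbouring bins are not independent, which Fisher's exact test ignores, so its p-values may be too small. Whether replicates share more than other pairs was not tested. The bin at 102640001 was the only bin that passed in all 3 groups, at 3.33 times the expected value in thymocytes, 3.52 and 3.05 in WT muscle, and 6.37 and 13.8 in GRko muscle. It was again the only such bin with the expected value fitted on each side (4.01 in thymocytes, 2.29 and 2.18 in WT muscle, 4.50 and 8.93 in GRko muscle). It lies in an interval without annotated genes, on the near side of Cd180. The bin at 102360001 passed in both muscle groups, at 2.52 and 9.25 in WT and 5.22 and 10.9 in GRko muscle, and stood at 1.47 in thymocytes. Fitted on each side, it fell to 1.63 in WT replicate 1 and rose to 2.04 in thymocytes, so it does not set muscle apart. The bins highest above expectation lay near the edge of the region within Mast4, at 103230001 for WT muscle (2.40 and 30.9 in replicates 1 and 2), 103080001 for GRko muscle (9.43 and 53.3) and 103220001 for thymocytes (7.58), where few reads were expected. The mean for WT muscle, 16.7, rests on replicate 2. Others among the highest were 102350001, 102650001 and 101980001 in WT muscle (means 6.05, 5.96 and 4.54) and 102890001 and 102440001 in GRko muscle (means 5.21 and 4.82). In thymocytes they were 103180001 and 103110001 within Mast4 (7.27 and 4.50), 100490001 over Gtf2h2 and Ocln (3.95), and 102660001 (3.79). These lists rank bins within a group and do not set groups apart. The bin at 103220001 stood at 17.3 and 1.25 in WT and 13.3 and 1.47 in GRko muscle. That at 103180001 stood at 0.178 and 5.26 in WT and 0.183 and 22.3 in GRko muscle. At 100490001 no muscle library exceeded 0.577. Bins at 103230001 and 102650001 also passed in thymocytes (3.33 and 3.66), while that at 103080001 did not (0.107).

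More than 1.5 Mb from the bait, contacts were counted as covered fragments per 500 kb window. The muscle genotypes did not differ detectably there. With edgeR 0 of 165 windows passed, 7 had an unadjusted p under 0.05, and DESeq2 called 0. Among the windows with the smallest p were 35500001, over Cdyl and Rpp40 (log2 ratio of GRko over WT 0.96 ± 0.368, SE) and 53500001 (0.98 ± 0.424). In the other direction they were 63000001, over Aopep and Fancc (-1.03 ± 0.399), 44000001 (-1.15 ± 0.456) and 54500001, over Simc1 and Unc5a (-0.86 ± 0.392). In simulated data at this spread with 20 windows changed, 22% of those changed 2-fold and 73% of those changed 4-fold were recovered.

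Between DP thymocytes and WT muscle, 20 of 185 far windows passed in edgeR, 6 higher and 14 lower in thymocytes. That split changed with the minimum of reads: with at least 2 reads per covered fragment 24 of 151 windows passed, 15 higher and 9 lower, and with at least 10 reads, a limit added after the data were seen, 20 of 130, 11 higher and 9 lower. Of the 20 windows called, 14 could still be tested with at least 2 reads (6 higher and 8 lower) and 13 of them passed; with at least 10 reads 8 could be tested (5 higher and 3 lower) and 7 passed. The window at 23500001 to 24000000, which holds a cluster of histone genes, had 62 covered fragments in thymocytes and 8 and 13 in WT muscle (log2 ratio 1.49 ± 0.384, adjusted p = 0.0051), and reads from near-identical histone genes make this window less certain. Adjoining windows at 107000001 and 107500001, over Kif2a, a microtubule-depolymerising kinesin, and Zswim6, had log2 ratios of 1.35 ± 0.407 and 1.29 ± 0.439. The windows over Hmgcs1 and Ccl28 (119500001) and over Tert, the telomerase reverse transcriptase, and Slc6a3 (73500001) had log2 ratios of 1.17 ± 0.347 and 1.14 ± 0.361. None of these 4 windows passed when either WT replicate was left out, with adjusted p from 0.058 to 0.402, although the ratios stayed above 1. The 6 higher windows held a median of 7 protein-coding genes, against 0 in the 14 lower windows and 3 in all windows tested.

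Of the windows lower in thymocytes, that at 26500001 to 27000000, over Hdgfl1, had 2 and 13 covered fragments in GRko muscle, which did not enter the ratio. It had 15 and 11 in WT muscle. In thymocytes it had 0 of 9363 covered fragments, which allows a share of up to 0.032%. Against a floor of 3 fragments it was at least 9.43-fold lower (edgeR adjusted p = 0.00268, and 0.283 and 0.278 without WT replicate 1 and 2). The window at 47500001, without protein-coding genes, had 3 covered fragments in thymocytes (95% Wilson interval of the share 0.0109% to 0.0942%) and 24 and 12 in WT muscle. The windows at 82000001, 60000001 (over Gas1) and 69000001 (over Tent4a) had log2 ratios of -3.17 ± 0.593, -2.82 ± 0.452 and -2.49 ± 0.486. Of these 5 windows, those at 26500001, 47500001 and 69000001 held too few fragments with at least 2 reads to be tested. Their calls thus rest in part on fragments with a single read. Beyond 1.5 Mb these made up 1381 of 3022 covered fragments in WT replicate 2. They were 576 of 6244 in WT replicate 1 and 951 of 9363 in thymocytes. DESeq2 called 0 of these 185 windows and gave 11 with an unadjusted p under 0.05, and read counts gave 0 calls. Without WT replicate 1, 7 windows passed, 0 higher and 7 lower, and without WT replicate 2, 7 passed, 2 higher and 5 lower; 5 and 6 of them were among the 20. All 6 windows called higher were thus lost without WT replicate 1, and the histone window then had a log2 ratio of 0.62. Of the 5 lower windows named, only that at 60000001 passed both without WT replicate 1 and without WT replicate 2.

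**Figure D3:**
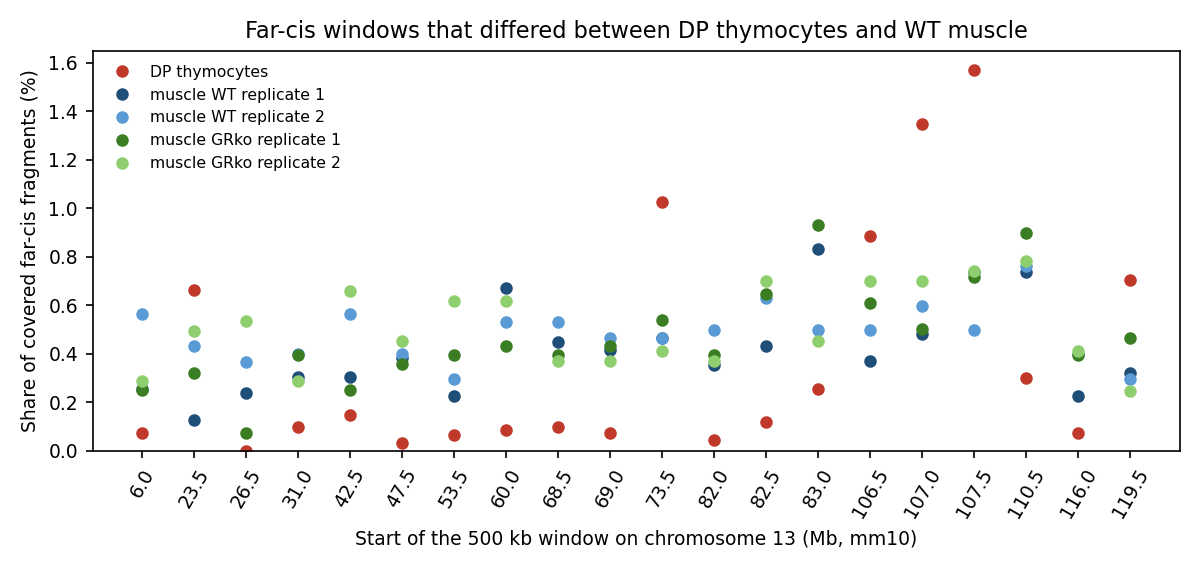
Share of covered far-cis fragments (%) in the 20 windows of 500 kb that passed between DP thymocytes and WT muscle, by window start in Mb, with 1 point per library. Thymocytes hold 1.57% in the window at 107500001 and 0 in that at 26500001; the GRko libraries did not enter the ratio.

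Windows holding lymphocyte-linked genes fixed before the data were examined (10 genes in 8 windows, among them Sox4, Gzma, Gzmk, Il6st and Map3k1) had a median log2 ratio of thymocytes over WT muscle of 0.63, with 7 of 8 above 0. That median lay at percentile 99.4 of 10000 random sets of windows, and at 98.6 among sets matched on the number of genes and 95.5 among sets matched on mean share. Windows holding muscle-linked genes (7 genes in 7 windows, Actn2, Ryr2, Cmya5, Mef2c, Fbp2, Fst and Thbs4) had a median of 0.26, with 5 of 7 above 0, at percentile 89.8, and 84.0 and 78.3 in the matched sets. The percentile of the lymphocyte-linked windows was 95.0 without WT replicate 1, 91.1 in 250 kb windows and 73.2 with reads, and that of the muscle-linked windows was 30.8 with reads. The windows of Map3k1, Il6st, and Gzma with Gzmk lie close together, at 111500001, 112000001 and 113000001 (log2 ratios 0.54, 0.82 and 0.95). The random sets were not matched on position, so a single regional difference may count more than once. The percentiles describe these libraries and are not tests. The window of Il6st had 150 covered fragments in thymocytes and 66 and 23 in WT muscle (log2 ratio 0.82). That of Ryr2, the cardiac ryanodine receptor, had 5 against 14 and 7 (log2 ratio -2.03). Thymocytes had 9363 covered far fragments in all, and the WT libraries 6244 and 3022.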

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

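All 10 kb bin comparisons stayed at 0 calls in edgeR, except that DESeq2 called 4 bins between genotypes and 6 between thymocytes and WT muscle, and 100 kb bins, chosen after seeing the data, called 3 between thymocytes and WT muscle; between genotypes they called 0, and 0 to 1 leaving out each replicate. TMM moved the log2 ratios of single bins by a median of 0.22 between genotypes and of -0.13 between thymocytes and WT muscle. Replicate numbers name no shared animal or batch in the labels. In muscle they match the read length after trimming, 29 nt for replicate 1 and 23 nt for replicate 2. A replicate block is thus also a block of read length. Replicate 1 libraries of both genotypes deviated from their group means with r = 0.0105 over bins and 0.348 over far windows. With the number as a replicate block, 0 bins, 0 genes and 0 far windows were called between genotypes, and the log2 ratio became -0.70 for Cdk7, -2.40 for Taf9, -0.95 for Gtf2h2 and -0.0031 for Cd180. The far windows called between thymocytes and WT muscle numbered 0 with DESeq2, 0 with reads, 12 in 250 kb windows, 12 without a filter, 41 against the mean of all muscle libraries, and 7 to 33 leaving out each replicate. The cause of the difference between tools was not tested. The higher-side difference was -2.81 points between genotypes and -27.2 for thymocytes against WT muscle with 25 kb left out, -0.028 and -17.9 with covered fragments, and -1.30 and -19.7 with fragments of at least 10 reads. Contact peaks in WT muscle, GRko muscle and thymocytes numbered 28, 22 and 64 at a threshold of 1.5, 5, 5 and 11 at 3, and 8, 6 and 10 in 20 kb bins. With a single replicate they numbered 44 to 50 in WT and 46 to 47 in GRko muscle, since fewer libraries had to pass. Among fixed genes the count of calls was 0 to 1 in either comparison leaving out each replicate. Ratios between genotypes turned sign with 20 kb bins for Cdk7 (-0.21), Taf9 (-5.16), Rad17 (0.34) and Ocln (1.62), and with DESeq2 for Taf9 (-0.10). Leaving out each replicate they ran from -0.86 to 2.31 for Cenph, -2.91 to 1.25 for Cdk7, -9.15 to 1.14 for Taf9, -1.16 to 14.98 for Marveld2, -1.66 to 1.90 for Ocln, -0.23 to 1.76 for Gtf2h2 and -1.64 to 1.43 for Cd180. For thymocytes over WT muscle they turned with DESeq2 for Ccnb1 (-0.068) and Ak6 (-0.23) and with 20 kb bins for Cd180 (-0.19), and ran from -0.79 to 3.90 for Ccnb1, -0.38 to 3.71 for Ak6 and -0.19 to 8.87 for Gtf2h2. The bin at 100560001 had -1.30 for thymocytes over WT replicate 1 and GRko replicate 1 together, the muscle libraries of the same read length; GRko replicate 1 held 10100 of its reads and WT replicate 1 held 10. The median of muscle-linked windows was 0.013 with reads (percentile 30.8) and 0.032 to 0.35 leaving out each WT replicate. That of lymphocyte-linked windows was 0.24 in 250 kb windows (percentile 91.1), 0.81 with reads (percentile 73.2, the lowest, although the median is the highest), 0.35 without WT replicate 1 (percentile 95.0), and 0.60 without WT replicate 2. The cause of these changes was not tested.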

Other observations

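All tests of explanations below were chosen after the results were seen. The lower share of thymocyte contacts on the side of Cd180 and Mast4 was set against a few fragments with very many PCR copies, library complexity and read length. With each fragment of at least 10 reads counted once, thymocytes lay 15.9 percentage points below the lowest muscle library. With the 1062 fragments of most reads from each library they lay 19.6 points below it, at 48.2% against 67.8% to 73.2%, although WT replicate 1, the most complex muscle library, was the lowest muscle library over all covered fragments (63.1%). At the same read length the gap was 20.1 points, so the tables argue against all 3 as the whole cause. That tissue sets the side of contact is a hypothesis from 1 thymocyte library; tissue, age and preparation (nuclei from muscle, sorted cells from thymus) differed together and were not told apart by any test.

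WT muscle replicate 2 and both GRko libraries shared fragments with a single read. Of far fragments with at least 1000 reads in any of these 3 libraries, 10.7% to 22.8% had exactly 1 read in another of them, against 0 to 1.02% in the 14 other ordered pairs, a gap of 9.66 percentage points; for fragments with fewer reads, from 100 up, it was 1.27% to 7.19%. Reads passed between libraries handled or sequenced together may account for this. Contacts shared by muscle are argued against, since at most 6.45% of these strong fragments had any read in WT replicate 1, which covered more fragments. Such reads would make WT replicate 2 look more like GRko muscle, and counts of covered fragments are more exposed to them than reads are.

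Across all 230 far windows, the ratio of thymocytes over WT muscle rose with the number of protein-coding genes (Spearman's rho 0.466, Pearson's r 0.306, across windows, which are not independent). A circular-shift permutation gave p = 0.00435, the smallest it can give, and 0.00559 adjusted over 18 relations; GRko over WT muscle had rho 0.00923 (p = 0.874). An even background of weakly covered fragments in muscle would remove the relation among fragments with at least 10 reads, where rho was 0.393. Reads passed between the 3 libraries would remove it against WT replicate 1, where rho was 0.442. Both values argue against these as the whole cause, although with reads rho was 0.248, and 0.128 (p = 0.0696) against WT replicate 2 alone, while tissue, age and preparation stay open, untested. A minimum of 10 reads does not remove an even background whose fragments carry more reads, so that background stays open too.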
